A study of Arabidopsis thaliana with 16 samples.

How the data were processed

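Whole Arabidopsis thaliana seedlings of Col-0 and seu-6 were compared in 2 experiments, each with its own mock in liquid half-strength MS medium. One used 14-day seedlings and 300 mM NaCl for 15 min, the other 10-day seedlings and 250 mM sorbitol for 6 h. Per the labels' protocols, plants grew under 16 h light and 8 h dark, RNA was taken with Trizol and treated against DNA, poly(A) RNA was selected on beads, and libraries were made with a NEXTflex kit. Each of the 8 groups has 2 biological replicates, and every one of the 16 libraries was assigned to its group from its label.

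The values used are raw counts per gene, deposited by the authors as 1 table per library. Per the submitters' processing notes, reads were aligned to TAIR10 with HISAT2 2.2.1, counted with HTSeq 0.13.5 and compared with DESeq2. Strand setting, annotation release and read filters are not given in the sources used here. Each table ends with 5 summary lines of reads outside the gene counts, which were left out of library sizes and tests and hold between 8.78% and 12.7% of reads. Gene counts per library lay between 39756463 and 42676953, and between 23295 and 24520 genes had at least 1 count. Replicates of a group correlated across genes with r between 0.986 and 0.992 on log2 CPM. Among genes with a mean above 5 CPM, the SD per library, taken across genes from the log2 difference between replicates, lay between 0.102 and 0.117. Floors of 3 counts cover counting error only. Gene symbols were taken from a TAIR10.1 reference, used for names alone, in which 32548 of the 32833 loci were found and 285 were not.

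All values below were computed from these counts with R 4.3.3. Each experiment was fitted on its 8 libraries with the quasi-likelihood F test of edgeR 4.0.16 (robust option, 4 residual degrees of freedom), after scaling by TMM and removal of low counts by filterByExpr, with 1 mean per group and no block. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called higher or lower. The comparisons were each treatment against its mock within each genotype, seu-6 against Col-0 within each medium, the difference between the 2 genotypes' responses (interaction), and the mean response of both genotypes. SEU was examined first in every library. Treatment-responsive genes were taken from the mean response, which is independent of the interaction by design. Overlaps that share a group of libraries were set against 20 simulations with no genotype effect and against the overlap of independent lists.

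Gene lists, 23 of them with 394 members used of 397 written, were fixed before the data were examined, as were the comparisons, the tests, the alternatives and the rule for genes named. They were tested with camera of limma 3.58.1 with a preset correlation of 0.01, adjusted over the 23 lists, and again with an estimated correlation and with fry. For the sets of responsive genes the camera p was adjusted over the 4 sets. The rule for genes named takes the 5 largest rises and falls with an average log2 CPM of at least 2, up to 4 members of each list with the smallest adjusted p, and for the interactions the 10 genes of smallest p. The text prints part of these. Lists of seed storage, late embryogenesis, embryo regulator and phosphate starvation genes were added after the results were seen.

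Alternatives were DESeq2 1.42.0, its size factors in edgeR, no filter on low counts, the replicate number as a block, all 16 libraries in 1 fit, and each library left out in turn, where a group left with 1 library is taken to vary like the others. Leaving out each library for the list tests and for SEU was added later. The fits were tested on simulated counts with 200 changed genes. For the NaCl response of Col-0, with 21686 genes, 28% of changes of 1.2-fold, 80% of 1.5-fold, 92% of 2-fold and 100% of 4-fold were recovered, and 10.8% of the calls were unchanged genes. For the NaCl interaction the shares recovered were 10%, 74%, 86% and 98%, with 6.37% unchanged genes among the calls. For the sorbitol response of Col-0, with 21348 genes, they were 44%, 82%, 98% and 100%, with 5.18%, and for the sorbitol interaction 18%, 62%, 94% and 100%, with 6.51%. A planted list was called in each, and no other of the 23 lists. Genes were simulated independently, so this does not show how correlation between genes affects the list calls.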

Results

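Transcript levels were measured by poly(A) RNA sequencing of whole Arabidopsis seedlings of the wild type Col-0 and of seu-6, a mutant of SEUSS (SEU), which encodes a transcriptional co-regulator. In the first experiment 14-day seedlings were moved into liquid half-strength MS medium, alone (mock) or with 300 mM NaCl, for 15 min. In the other, 10-day seedlings were kept in the liquid medium, alone or with 250 mM sorbitol, for 6 h. Each of the 8 groups of genotype and treatment has 2 biological replicates, 16 libraries in total. Gene counts per library lay between 39756463 and 42676953. The series title names the condensation of SEUSS and tolerance of hyperosmotic stress. The comparisons therefore ask how each genotype responded, how the genotypes differed, and whether the responses differed between them. Values after a gene are log2 fold changes from edgeR ± a standard error, with 2 libraries per group. The standard error was derived from the log2 fold change and its F value. It rests on a spread estimated over the libraries of the experiment and across genes, and is not the spread of the 2 libraries of a group. Gene lists were fixed before the data were examined, and a list call with no further p stayed under 0.05 with an estimated correlation between genes. The camera p printed first uses the preset correlation and can be far smaller. Between the 2 mocks of Col-0, early ZAT, WRKY and MYB factors had a camera adjusted p of 8.8e-38, and of 1.0e-04 with an estimated correlation. Levels of genes with close copies, such as KIN2, PIP2A, PIP2B, AOC1 and PCNA1, are uncertain. Reads that did not align uniquely were set apart in a summary line, so reads of such genes may be missing from their counts. Levels of overlapping or antisense genes are uncertain as well.

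SEU transcript levels separated the genotypes in every library. The mean in Col-0 was 42.6 ± 2.81 CPM (SD, n = 2) in the 15 min mock, 46.8 ± 1.98 under NaCl, 52.6 ± 2.38 in the 6 h mock and 54.0 ± 0.626 under sorbitol. The corresponding seu-6 means were 0.960 ± 0.287, 0.959 ± 0.045, 0.554 ± 0.101 and 0.510 ± 0.154 CPM, from 17 to 45 counts per library. SEU (AT1G43850) was lower in seu-6 by 44.1-fold and 49.4-fold in the 15 min mock and under NaCl, and by 94.5-fold and 106-fold in the 6 h mock and under sorbitol. The edgeR adjusted p values were 2.8e-52, 1.0e-53, 7.5e-47 and 4.9e-47. No change of SEU was detected in Col-0 under NaCl (edgeR adjusted p = 0.20) or sorbitol (0.53).

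**Figure D1:**
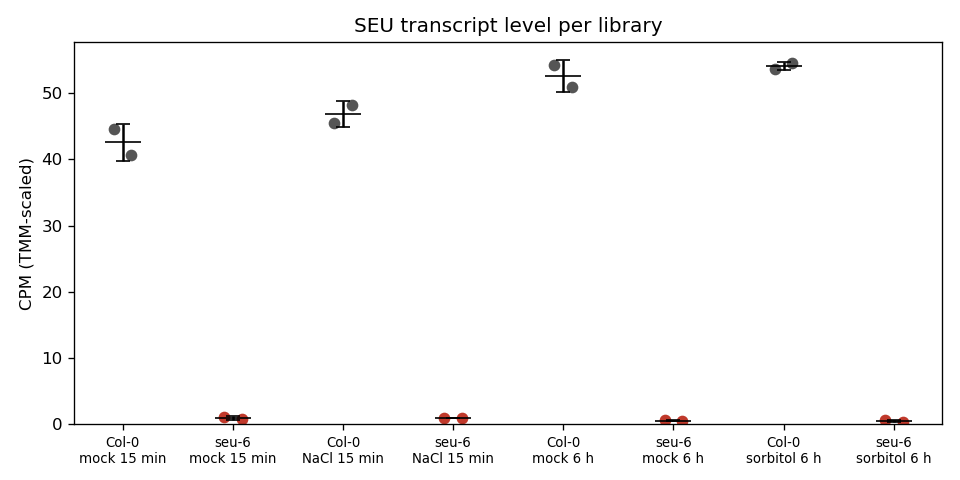
Each point is the SEU level of 1 library in CPM, the horizontal mark is the group mean and the bar is ± 1 SD of the 2 libraries, with Col-0 in grey and seu-6 in red. Col-0 groups have means between 42.6 and 54.0 CPM, and seu-6 group means lie below 1 CPM.

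NaCl for 15 min in Col-0 lowered transcripts of early stress-signalling genes relative to the 15 min mock. The lists of these genes were themselves higher in that mock than in the 6 h mock of Col-0. Transcription factor genes of early stress responses fell, among them STZ (AT1G27730, -1.64 ± 0.033), ZAT11 (AT2G37430, -2.73 ± 0.14) and WRKY40 (AT1G80840, -0.95 ± 0.031). Touch-responsive TCH4 (AT5G57560, -1.43 ± 0.024) and the calmodulin-like CML38 (AT1G76650, -1.75 ± 0.040) fell as well, as did ERF6 (AT4G17490, -1.53 ± 0.038) and DDF1 (AT1G12610, -1.84 ± 0.064) of the ERF family. Jasmonate genes that fell included the repressor genes JAZ1 (AT1G19180, -1.02 ± 0.028) and JAZ7 (AT2G34600, -2.29 ± 0.079) and the lipoxygenase gene LOX4 (AT1G72520, -1.09 ± 0.030). The highest edgeR adjusted p of these 10 genes was 4.4e-31. Of 26 early ZAT, WRKY and MYB factors 24 fell and 1 rose (1 up and 24 down adjusted over the list alone), with a median of -0.72 (camera adjusted p = 1.6e-32). Touch and calcium genes fell in 14 of 15 cases (0 up and 14 down adjusted over the list alone), with a median of -0.43 (camera adjusted p = 9.2e-21). Among CBF/DREB and ERF factors 14 of 20 fell and 2 rose (2 up and 14 down adjusted over the list alone), with a median of -0.76 (camera adjusted p = 1.5e-17). For jasmonate genes 16 of 23 fell and 6 rose (6 up and 16 down adjusted over the list alone), with a median of -0.48 (camera adjusted p = 1.1e-11).

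Genes of proline, galactinol and raffinose metabolism rose as a list in Col-0 within the same 15 min, as did single genes of ABA and heat responses. HSFA6B (AT3G22830, 2.52 ± 0.13), a heat shock factor, and the NAC factor RD26 (AT4G27410, 1.06 ± 0.072) rose, together with NCED3 (AT3G14440, 1.76 ± 0.12), which encodes an enzyme of abscisic acid (ABA) synthesis. The raffinose synthase gene SIP1 (AT5G40390, 0.96 ± 0.060) and the beta-amylase gene BAM1 (AT3G23920, 0.50 ± 0.038) rose too, as did ERD5 (AT3G30775, 0.53 ± 0.030), whose product, proline dehydrogenase, degrades proline. The ABA receptor genes PYL4 (AT2G38310, -0.57 ± 0.042), PYL5 (AT5G05440, -0.87 ± 0.044) and PYL6 (AT2G40330, -1.28 ± 0.10) fell. Each of the 9 genes had an edgeR adjusted p of 1.0e-19 or lower. Proline, galactinol and raffinose genes rose in 9 and fell in 1 of 15 cases (10 up and 1 down adjusted over the list alone), with a median of 0.35 (camera adjusted p = 4.7e-07). Heat shock genes rose in 7 and fell in 2 of 14 (7 up and 2 down adjusted over the list alone), with a median of 0.39 (camera adjusted p = 0.0028, adjusted p = 0.15 with an estimated correlation). ABA receptors fell in 4 and rose in 2 of 9 (2 up and 5 down adjusted over the list alone; camera adjusted p = 0.024, adjusted p = 0.16 with an estimated correlation), a call lost without NaCl replicate 2 of Col-0 or of seu-6 (camera adjusted p = 0.063 and 0.050). ABA and dehydration effectors went both ways, 9 of 24 higher and 5 lower (9 up and 5 down adjusted over the list alone; camera adjusted p = 0.11). Beside these groups, light harvesting and Rubisco genes fell in 18 of 21 cases (0 up and 18 down adjusted over the list alone; camera adjusted p = 1.1e-06, adjusted p = 0.29 with an estimated correlation). Root tissue markers fell in 9 of 18 (0 up and 9 down adjusted over the list alone; camera adjusted p = 0.0013, adjusted p = 0.098 with an estimated correlation). Among them was CASP1 (AT2G36100, -1.36 ± 0.075) of the Casparian strip, with an edgeR adjusted p of 2.1e-28. In all, edgeR called 3482 genes higher and 3893 lower of 22066 tested. Without replicate 2 of NaCl-treated Col-0 the number called higher was 2315.

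In seu-6 jasmonate, touch and early transcription factor genes fell within 15 min of NaCl, and single heat and drought genes rose. The factors HSFA6B (2.26 ± 0.14) and DREB2A (AT5G05410, 2.26 ± 0.048), which act in heat and drought responses, rose, as did the chaperone gene HSP70 (AT3G12580, 1.03 ± 0.059). Jasmonate genes that fell included CYP94C1 (AT2G27690, -2.47 ± 0.055), for an enzyme of jasmonate turnover, JAZ8 (AT1G30135, -2.86 ± 0.13) and OPR3 (AT2G06050, -1.04 ± 0.028), for a step of jasmonate synthesis. Among these 6 genes the highest edgeR adjusted p was 4.1e-26. Heat shock genes rose in 8 of 14 cases (9 up and 0 down adjusted over the list alone), with a median of 0.82 (camera adjusted p = 1.9e-07, adjusted p = 0.050 with an estimated correlation). Jasmonate genes fell in 21 and rose in 0 of 23 (1 up and 21 down adjusted over the list alone), with a median of -1.01 (camera adjusted p = 2.2e-51). ZAT, WRKY and MYB factors fell in 21 and rose in 2 of 26 (2 up and 23 down adjusted over the list alone; camera adjusted p = 1.7e-22). Touch genes fell in 12 of 15 (0 up and 14 down adjusted over the list alone; camera adjusted p = 2.7e-18). Aquaporins fell in 11 and rose in 3 of 18 (3 up and 11 down adjusted over the list alone; camera adjusted p = 8.4e-07, adjusted p = 0.077 with an estimated correlation). Among them was PIP2B (AT2G37170, -0.81 ± 0.036), with an edgeR adjusted p of 1.5e-34. Ion transport genes fell in 6 of 16 (0 up and 6 down adjusted over the list alone; camera adjusted p = 0.0050, adjusted p = 0.077 with an estimated correlation), beside root markers that fell in 10 and rose in 1 of 18 (1 up and 11 down adjusted over the list alone; camera adjusted p = 1.4e-05, adjusted p = 0.050 with an estimated correlation). Light harvesting and Rubisco genes fell in 16 of 21 (0 up and 20 down adjusted over the list alone, camera adjusted p = 1.4e-06, adjusted p = 0.27 with an estimated correlation). Of 2654 genes called higher and 3950 lower, 1670 and 2718 were called the same way in Col-0. Independent lists would share 418.8 and 696.9.

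Between genotypes in the 15 min mock, defence transcripts were higher in seu-6, and stress-factor, jasmonate, dehydration, auxin and cell wall transcripts were lower. The pathogenesis-related gene BGL2 (AT3G57260, 2.31 ± 0.078) and the immune regulator SARD1 (AT1G73805, 1.32 ± 0.054) were among the higher, while ERF2 (AT5G47220, -0.98 ± 0.049) and PIN3 (AT1G70940, -0.64 ± 0.053), an auxin transporter gene, were lower. The xyloglucan enzyme genes XTH19 (AT4G30290, -1.45 ± 0.057) and XTH18 (AT4G30280, -0.80 ± 0.035) were lower, although they and XTH17 are close copies, which leaves the assignment of reads between them uncertain. The myrosinase gene TGG2 (AT5G25980, -2.69 ± 0.043) and the phosphate starvation genes SPX3 (AT2G45130, -2.64 ± 0.22) and IPS1 (AT3G09922, -2.62 ± 0.14) had some of the largest falls. None of the 9 genes had an edgeR adjusted p above 6.2e-18. Salicylate and immune genes were higher in 12 and lower in 1 of 18 cases (12 up and 1 down adjusted over the list alone), with a median of 0.73 (camera adjusted p = 8.6e-18). CBF/DREB and ERF factors were lower in 18 of 20 (0 up and 18 down adjusted over the list alone), with a median of -0.67 (camera adjusted p = 5.9e-27). Cell wall enzymes were lower in 10 of 14 (1 up and 10 down adjusted over the list alone), with a median of -0.38 (camera adjusted p = 2.1e-08). Jasmonate genes were lower in 17 and higher in 4 of 23 (4 up and 17 down adjusted over the list alone), with a median of -0.24 (camera adjusted p = 3.1e-10). ABA effectors were lower in 14 and higher in 2 of 24 (2 up and 14 down adjusted over the list alone), with a median of -0.27 (camera adjusted p = 2.0e-07). The ZAT, WRKY and MYB list held 17 lower and 6 higher of 26 (6 up and 18 down adjusted over the list alone; camera adjusted p = 2.0e-07), and touch genes 8 lower and 2 higher of 15 (3 up and 9 down adjusted over the list alone; camera adjusted p = 2.1e-06). Auxin genes were lower in 12 of 24 (0 up and 16 down adjusted over the list alone; camera adjusted p = 8.4e-06). Ethylene genes were lower in 8 and higher in 2 of 14 (2 up and 8 down adjusted over the list alone; camera adjusted p = 4.9e-04). Beside these groups, root markers were lower in 10 of 18 (0 up and 11 down adjusted over the list alone; camera adjusted p = 5.3e-04, adjusted p = 0.069 with an estimated correlation). Light harvesting genes were higher in 15 and lower in 2 of 21 (16 up and 2 down adjusted over the list alone; camera adjusted p = 2.0e-07, adjusted p = 0.27 with an estimated correlation). In total edgeR called 3084 genes higher and 2852 lower.

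Under NaCl, as in the mock, jasmonate and dehydration transcripts were lower in seu-6 than in Col-0, and defence transcripts were higher. JAZ10 (AT5G13220, -2.02 ± 0.063) and the jasmonate synthesis gene AOC1 (AT3G25760, -1.48 ± 0.046) were lower, as were the dehydration genes LTI78 (AT5G52310, -0.87 ± 0.030) and KIN2 (AT5G15970, -0.92 ± 0.036) and the proline synthesis gene P5CS1 (AT2G39800, -1.18 ± 0.044). PR1 (AT2G14610, 4.32 ± 0.041), a marker of salicylate signalling, was higher. The highest edgeR adjusted p of these 6 genes was 6.5e-38. Jasmonate genes were lower in 21 and higher in 2 of 23 cases (2 up and 21 down adjusted over the list alone), with a median of -0.90 (camera adjusted p = 6.8e-40). ABA effectors were lower in 15 and higher in 2 of 24 (2 up and 16 down adjusted over the list alone), with a median of -0.49 (camera adjusted p = 9.1e-13). Immune genes were higher in 14 and lower in 3 of 18 (14 up and 3 down adjusted over the list alone; camera adjusted p = 3.9e-19). Aquaporins were lower in 16 of 18 (0 up and 17 down adjusted over the list alone; camera adjusted p = 1.8e-11, adjusted p = 0.052 with an estimated correlation), beside root markers lower in 11 of 18 (0 up and 12 down adjusted over the list alone; camera adjusted p = 2.0e-05, adjusted p = 0.058 with an estimated correlation). Light harvesting and Rubisco genes were higher in 13 and lower in 2 of 21 (13 up and 3 down adjusted over the list alone, camera adjusted p = 7.4e-07, adjusted p = 0.29 with an estimated correlation). In total 2999 genes were called higher and 3547 lower.

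The test of the difference between the NaCl responses found a lower log2 response of jasmonate genes in seu-6. CBF/DREB and ERF genes had a higher one. Since the jasmonate list fell in both genotypes, its lower response was a larger median fall in seu-6. The CBF/DREB and ERF list fell in Col-0 and was already lower in the seu-6 mock, so its higher response need not mean induction. STZ, ERF6 and CML38 fell in Col-0 by more than their difference between genotypes, so in seu-6 they fell less. OPR3 (-0.85 ± 0.039), CYP94C1 (-1.45 ± 0.073), LOX2 (AT3G45140, -0.84 ± 0.045) and LOX3 (AT1G17420, -0.71 ± 0.041) had the lower response. DREB2A (1.08 ± 0.066) and ERF6 (0.51 ± 0.054), the zinc finger genes STZ (0.86 ± 0.046) and RHL41 (AT5G59820, 1.19 ± 0.094), and the calmodulin-like genes CML38 (0.84 ± 0.056) and TCH2 (AT5G37770, 0.57 ± 0.048) had the higher. The dehydration genes LTI78 (-0.62 ± 0.042) and ERD7 (AT2G17840, -0.42 ± 0.034) and the aquaporin gene PIP2A (AT3G53420, -0.30 ± 0.035) had a lower response, as did ABR1 (AT5G64750, -2.54 ± 0.14) and JRG21 (AT3G55970, -2.08 ± 0.26) outside the lists. ORA47 (AT1G74930, 1.89 ± 0.11), a regulator of jasmonate synthesis, and the Nudix hydrolase genes NUDT4 (AT1G18300, 1.76 ± 0.074) and NUDT21 (AT1G73540, 1.40 ± 0.058) had a higher one. Each of the 18 genes had an edgeR adjusted p of 6.1e-10 or lower. Jasmonate genes had a lower response in 17 and a higher one in 1 of 23 cases (1 up and 18 down adjusted over the list alone), with a median of -0.57 (camera adjusted p = 1.1e-55). CBF/DREB and ERF factors had a higher response in 12 of 20 (15 up and 0 down adjusted over the list alone), with a median of 0.45 (camera adjusted p = 9.8e-26). The ZAT, WRKY and MYB list held 9 higher and 4 lower of 26 (11 up and 4 down adjusted over the list alone; camera adjusted p = 4.4e-08, adjusted p = 0.060 with an estimated correlation). ABA effectors held 11 lower and 2 higher of 24 (2 up and 11 down adjusted over the list alone; camera adjusted p = 6.4e-06, adjusted p = 0.11 with an estimated correlation), and aquaporins 13 lower of 18 (0 up and 14 down adjusted over the list alone; camera adjusted p = 1.2e-12, adjusted p = 0.062 with an estimated correlation). Root markers had a lower response in 2 of 18 (0 up and 5 down adjusted over the list alone), with a median of -0.24 (camera adjusted p = 0.047, adjusted p = 0.21 with an estimated correlation). That call was lost without replicate 1 of the Col-0 or seu-6 mock (camera adjusted p = 0.084 and 0.11), NaCl replicate 1 of Col-0 (0.068) or NaCl replicate 2 of seu-6 (0.076). In total 572 genes had a higher and 1013 a lower response. The latter number was 619 without replicate 1 and 647 without replicate 2 of NaCl-treated Col-0, and 657 without replicate 1 of its mock.

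Over all NaCl-responsive genes the difference between genotypes was small. The 4440 genes called up in the mean response of both genotypes had a median difference of -0.055, and 60.4% of them responded less in seu-6 (camera adjusted p = 0.019). That call was lost without seu-6 mock replicate 1 or 2 (medians -0.035 and -0.033) and without NaCl replicate 1 or 2 of seu-6 (medians -0.045 and -0.034). The 5050 genes called down had a median of -0.012 and no call (camera adjusted p = 0.68). That median lay between -0.025 without NaCl replicate 2 of seu-6 and 0.036 without NaCl replicate 1 of Col-0, so its sign is not settled. Of the genes higher under NaCl in Col-0, 868 were lower in seu-6 than in Col-0 under NaCl, and 1111 of those lower were higher in seu-6. Independent lists would share 559.7 and 529.1. In the same direction, 313 were higher in both comparisons and 1049 lower in both, where independent lists would share 473.2 and 625.8. In 20 simulations with no genotype effect the overlaps averaged 0.05 and 0.35, but the simulated genotype comparison called 0.9 genes on average. They therefore do not measure what shared libraries add. The 2 libraries of NaCl-treated Col-0 enter both sides and cannot be divided further, so part of the excess may come from sharing them. Without replicate 1 or 2 of that group the first overlap was smaller. At least 1 of the 2 lists behind it was then smaller too, so 559.7 is not the number to set beside it.

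**Figure D2:**
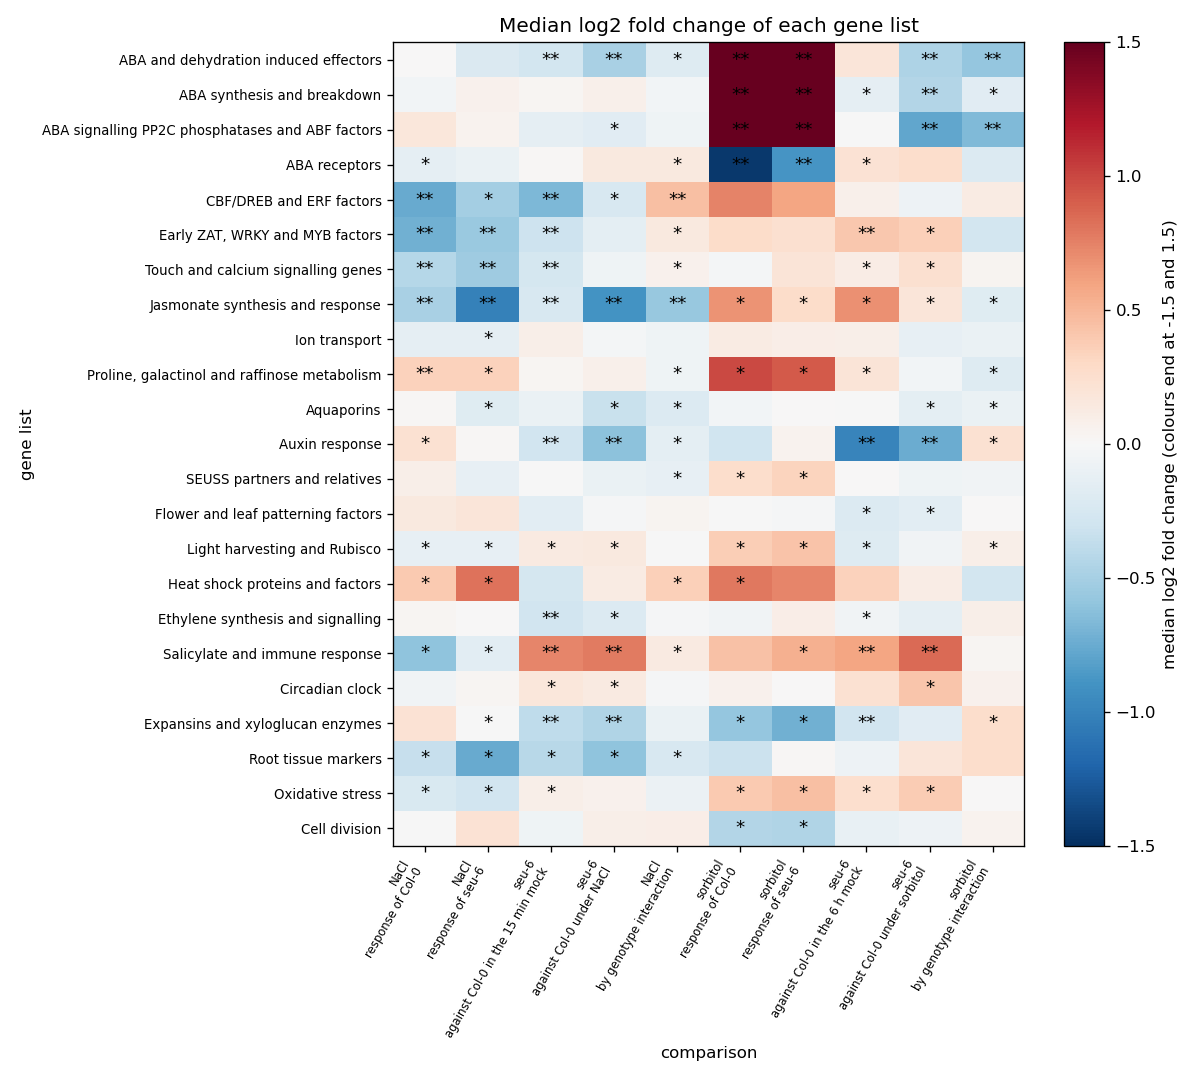
Colour gives the median log2 fold change of each gene list in each comparison, on a scale that ends at -1.5 and 1.5. One star marks a camera adjusted p under 0.05 with the preset correlation, and a double star the same also with an estimated correlation, as for the jasmonate list in the NaCl by genotype interaction (median -0.57).

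Sorbitol for 6 h in Col-0 raised ABA-responsive transcripts and lowered ABA receptor transcripts. Dehydration genes that rose included LTI78 (3.72 ± 0.033), RD20 (AT2G33380, 5.82 ± 0.055) and LTI65 (AT5G52300, 9.31 ± 0.087). TSPO (AT2G47770) had no counts in the Col-0 mock and was at least 599-fold higher under sorbitol, against a floor of 3 counts per library. PP2CA (AT3G11410, 3.54 ± 0.042), ABI1 (AT4G26080, 2.59 ± 0.036) and HAI2 (AT1G07430, 8.61 ± 0.16), which encode phosphatases that restrain ABA signalling, rose. So did NCED3 (4.65 ± 0.083) and ABA1 (AT5G67030, 1.82 ± 0.034) of ABA synthesis, while the receptor genes PYL6 (-4.50 ± 0.096) and PYL4 (-3.15 ± 0.053) fell. Among these 10 genes the highest edgeR adjusted p was 1.7e-45. All 24 ABA and dehydration effectors rose (24 up and 0 down adjusted over the list alone), with a median of 3.45 (camera adjusted p = 3.3e-94). All 16 PP2C and ABF genes rose (16 up and 0 down adjusted over the list alone), with a median of 3.47 (camera adjusted p = 9.0e-45). ABA synthesis and breakdown genes rose in 12 of 12 cases (12 up and 0 down adjusted over the list alone; camera adjusted p = 1.6e-10), the CYP707A genes for ABA breakdown among them. ABA receptors fell in 7 and rose in 2 of 9 (2 up and 7 down adjusted over the list alone), with a median of -1.44 (camera adjusted p = 2.7e-09).

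Single genes of metabolism, cell walls and replication also changed under sorbitol in Col-0. The proline synthesis gene P5CS1 (5.31 ± 0.039), the galactinol synthase gene GolS2 (AT1G56600, 6.81 ± 0.15) and the jasmonate-responsive VSP2 (AT5G24770, 3.35 ± 0.044) and LOX2 (2.44 ± 0.038) rose. The wall-modifying XTH4 (AT2G06850, -2.54 ± 0.037) and EXPA1 (AT1G69530, -1.34 ± 0.040) and the replication gene PCNA1 (AT1G07370, -1.51 ± 0.11) fell, as did the Rubisco small-subunit gene RBCS1B (AT5G38430, -2.26 ± 0.051), whose near-identical copies leave its own level uncertain. None of the 8 genes had an edgeR adjusted p above 1.0e-19. Proline and raffinose genes rose in 11 and fell in 4 of 15 cases (11 up and 4 down adjusted over the list alone; camera adjusted p = 3.5e-07, adjusted p = 0.054 with an estimated correlation). Jasmonate genes rose in 14 and fell in 1 of 23 (14 up and 1 down adjusted over the list alone; camera adjusted p = 2.0e-08, adjusted p = 0.074 with an estimated correlation). Cell wall enzymes fell in 9 and rose in 2 of 14 (3 up and 9 down adjusted over the list alone; camera adjusted p = 1.9e-05, adjusted p = 0.054 with an estimated correlation), and cell division genes fell in 11 of 12 (0 up and 11 down adjusted over the list alone; camera adjusted p = 0.029, adjusted p = 0.22 with an estimated correlation). Light harvesting and Rubisco genes rose in 17 and fell in 4 of 21 (17 up and 4 down adjusted over the list alone; camera adjusted p = 0.012, adjusted p = 0.44 with an estimated correlation). Among 8 SEUSS partners and relatives 4 rose (4 up and 0 down adjusted over the list alone; camera adjusted p = 0.020, adjusted p = 0.22 with an estimated correlation). The light-signalling factor PIF4 (AT2G43010, 1.55 ± 0.039) was among these, with an edgeR adjusted p of 8.1e-42. Circadian clock genes held 7 higher and 6 lower of 15 (7 up and 6 down adjusted over the list alone; camera adjusted p = 0.44). In all, 6777 genes were called higher and 6739 lower of 21633 tested.

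Sorbitol in seu-6 raised the ABA effector and the PP2C and ABF lists. Seed storage protein transcripts were lower than in the seu-6 mock, the group in which alone they were abundant. LTI65 (8.08 ± 0.082) and P5CS1 (4.70 ± 0.038) rose. SESA3 (AT4G27160), an albumin gene, and CRU2 (AT1G03880), a cruciferin gene, had no counts under sorbitol and were at least 357-fold and 207.7-fold lower than in the seu-6 mock. Another cruciferin gene, CRA1 (AT5G44120, -5.95 ± 0.14), fell as well. The highest edgeR adjusted p of these 3 genes was 1.6e-43. All 24 ABA effectors rose (24 up and 0 down adjusted over the list alone), with a median of 3.09 (camera adjusted p = 2.3e-81). PP2C and ABF genes rose in 15 of 16 cases (15 up and 0 down adjusted over the list alone), with a median of 2.63 (camera adjusted p = 4.3e-38). ABA receptors fell in 6 and rose in 1 of 9 (1 up and 6 down adjusted over the list alone; camera adjusted p = 1.0e-09). Of 6255 genes called higher and 6284 lower, 5334 and 5226 were called the same way in Col-0, where independent lists would share 1959.5 and 1957.6.

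In the 6 h mock, seed storage transcripts were present in seu-6 and near absent from Col-0. CRU3 (AT4G28520), SESA3 and CRU2 had no counts in Col-0 and were at least 421-fold, 387-fold and 225-fold higher in seu-6, and CRA1 (8.29 ± 0.17) was higher too. The defence genes PR1 (4.05 ± 0.10), BGL2 (3.05 ± 0.11) and WRKY70 (AT3G56400, 1.57 ± 0.075) were higher. IAA29 (AT4G32280, -3.47 ± 0.14) and PIN3 (-1.10 ± 0.044) of the auxin list were lower, with the wall gene XTH15 (AT4G14130, -2.07 ± 0.063) and the myrosinase gene TGG2 (-3.15 ± 0.037). Each of the 8 genes had an edgeR adjusted p of 1.8e-26 or lower. Immune genes were higher in 14 of 18 cases (15 up and 0 down adjusted over the list alone), with a median of 0.59 (camera adjusted p = 6.1e-17). Auxin genes were lower in 19 of 24 (0 up and 20 down adjusted over the list alone), with a median of -0.99 (camera adjusted p = 6.8e-31). Cell wall enzymes were lower in 10 and higher in 1 of 14 (1 up and 10 down adjusted over the list alone; camera adjusted p = 1.9e-08). Oxidative stress genes were higher in 11 and lower in 2 of 19 (11 up and 2 down adjusted over the list alone; camera adjusted p = 1.1e-07, adjusted p = 0.082 with an estimated correlation). Beside these groups, light harvesting genes were lower in 17 and higher in 3 of 21 (3 up and 17 down adjusted over the list alone; camera adjusted p = 1.4e-05, adjusted p = 0.20 with an estimated correlation). In total 3461 genes were called higher and 2552 lower.

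**Figure D3:**
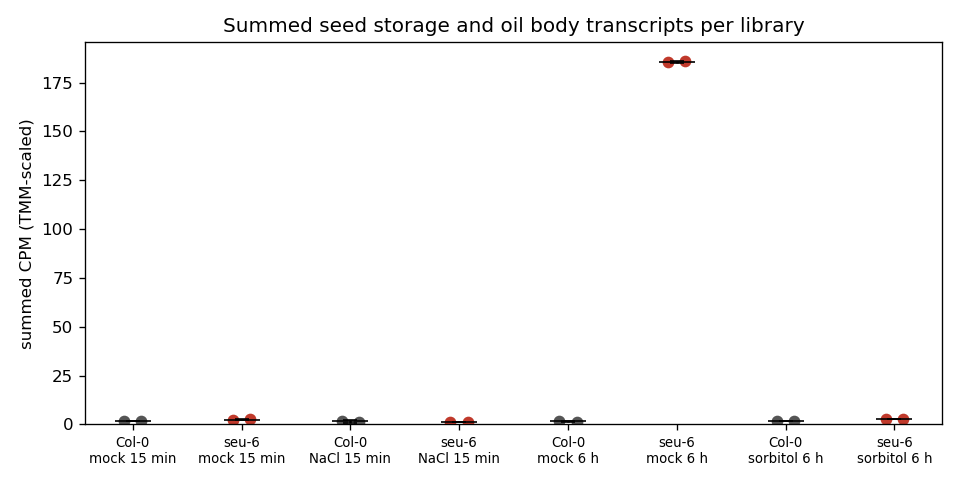
Points give the summed level of 12 seed storage and oil body transcripts in each library in CPM, the horizontal mark the group mean and the bar ± 1 SD of 2 libraries, with Col-0 in grey and seu-6 in red. Both seu-6 6 h mock libraries lie between 185.3 and 186.1 CPM, and the highest of the other 14 libraries is at 2.78.

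Under sorbitol, ABA-responsive and ABA synthesis transcripts were lower in seu-6 than in Col-0. The dehydration genes RD22 (AT5G25610, -1.04 ± 0.031), RD20 (-1.10 ± 0.039) and LTI78 (-0.47 ± 0.029) were lower, with HB-7 (AT2G46680, -1.02 ± 0.037), HAB1 (AT1G72770, -0.94 ± 0.040) and ABF3 (AT4G34000, -0.91 ± 0.038) of ABA signalling. NCED3 (-1.31 ± 0.063), P5CS1 (-0.95 ± 0.031) and the auxin-conjugating enzyme gene GH3.3 (AT2G23170, -3.44 ± 0.14) were lower too, while PR1 (4.47 ± 0.098) and BGL2 (3.91 ± 0.097) were higher. Among these 11 genes the highest edgeR adjusted p was 2.5e-21. ABA effectors were lower in 22 and higher in 1 of 24 cases (1 up and 22 down adjusted over the list alone), with a median of -0.46 (camera adjusted p = 1.3e-26). PP2C and ABF genes were lower in 14 and higher in 1 of 16 (1 up and 14 down adjusted over the list alone), with a median of -0.78 (camera adjusted p = 6.8e-22). ABA synthesis and breakdown genes were lower in 7 of 12 (0 up and 7 down adjusted over the list alone; camera adjusted p = 2.5e-07). Immune genes were higher in 14 of 18 (14 up and 0 down adjusted over the list alone; camera adjusted p = 4.8e-19). Flower and leaf patterning factors were lower in 7 and higher in 1 of 16 (2 up and 7 down adjusted over the list alone; camera adjusted p = 0.019, adjusted p = 0.15 with an estimated correlation), with a median of -0.16 but a mean of 0.0996. In total 3784 genes were called higher and 3756 lower.

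The test of the difference between the sorbitol responses found a lower log2 response of ABA genes in seu-6. The cold- and dehydration-induced COR15A (AT2G42540, -0.78 ± 0.051), KIN2 (-0.68 ± 0.047), COR47 (AT1G20440, -0.58 ± 0.041) and LTI30 (AT3G50970, -0.75 ± 0.052) had the lower response, with PP2CA (-0.81 ± 0.059), HB-7 (-0.96 ± 0.072) and ABF2 (AT1G45249, -0.74 ± 0.081) of ABA signalling. So did P5CS1 (-0.61 ± 0.050), the sucrose synthase gene SUS3 (AT4G02280, -1.46 ± 0.12) and CYP94B3 (AT3G48520, -2.34 ± 0.16) of jasmonate turnover. The wall genes XTH15 (1.34 ± 0.099), EXPA1 (0.60 ± 0.056) and EXPA8 (AT2G40610, 1.38 ± 0.14) had a higher response, as did IAA29 (1.68 ± 0.19). None of the 14 genes had an edgeR adjusted p above 5.0e-10. ABA effectors had a lower response in 20 and a higher one in 1 of 24 cases (1 up and 21 down adjusted over the list alone), with a median of -0.58 (camera adjusted p = 9.3e-32). PP2C and ABF genes had a lower response in 13 of 16 (0 up and 13 down adjusted over the list alone), with a median of -0.67 (camera adjusted p = 1.9e-18). Proline and raffinose genes held 8 lower of 15 (0 up and 8 down adjusted over the list alone; camera adjusted p = 9.9e-06, adjusted p = 0.093 with an estimated correlation). Cell wall enzymes held 7 higher and 2 lower of 14 (10 up and 2 down adjusted over the list alone; camera adjusted p = 7.7e-07, adjusted p = 0.069 with an estimated correlation). Auxin genes held 9 higher and 2 lower of 24 (10 up and 3 down adjusted over the list alone; camera adjusted p = 0.0025, adjusted p = 0.093 with an estimated correlation). In total 1216 genes had a higher and 1596 a lower response.

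The lower response in seu-6 was not limited to the ABA lists. Of the 7454 genes called up in the mean sorbitol response, 66.5% responded less in seu-6, with a median difference of -0.090 (camera adjusted p = 9.1e-09). The 7545 genes called down had a median difference of 0.074, with 63.8% responding less (camera adjusted p = 2.9e-07). Among genes higher under sorbitol in Col-0, 2371 were lower in seu-6 than in Col-0 under sorbitol, and 2013 of those lower were higher in seu-6. Independent lists would share 1177 and 1179. In the same direction, 906 were higher in both comparisons and 536 lower in both, where independent lists would share 1185 and 1170.0. The 20 simulations averaged 0.5 and 0.45, with 1.45 genes called in the simulated genotype comparison, so they do not measure what shared libraries add either. The 2 libraries of sorbitol-treated Col-0 enter both sides and cannot be divided further, so part of the excess may come from sharing them.

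**Figure D4:**
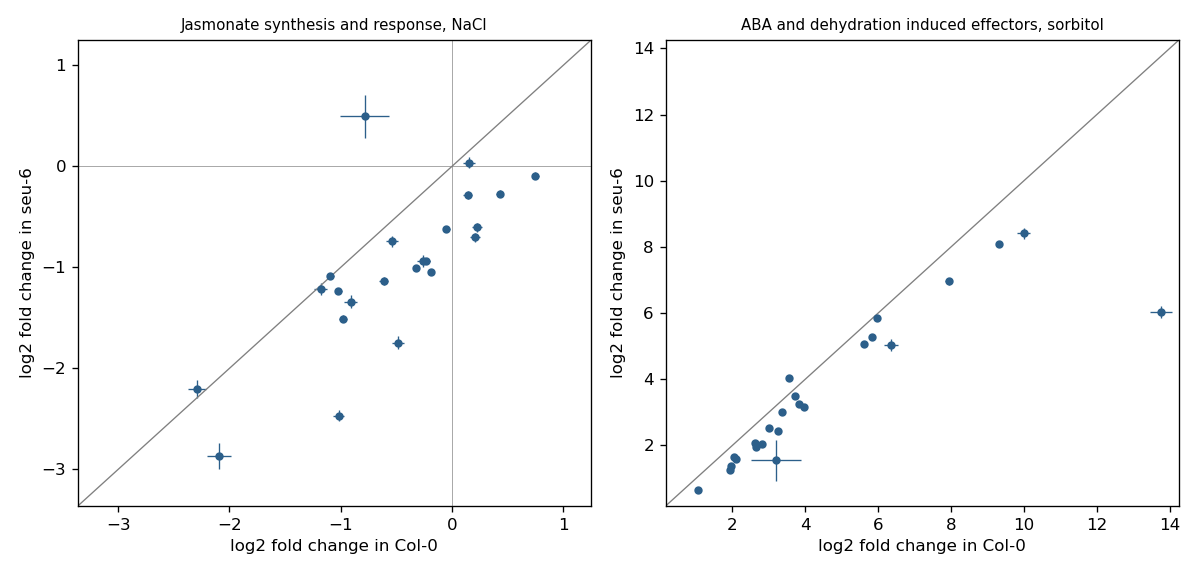
Each point is 1 gene, with its log2 fold change in Col-0 on the horizontal and in seu-6 on the vertical axis, bars of ± 1 standard error, and a grey line of equal response. Jasmonate genes under NaCl lie mostly below the line (median difference -0.57), as do ABA effectors under sorbitol (-0.58), where TSPO, farthest to the right, has no counts in the Col-0 mock, so its place there depends on the small count that the fit adds.

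Across experiments the genotype effect in the mocks was partly shared, with BGL2, PIN3 and TGG2 as examples named above. Of 21201 genes in both fits, 1402 were higher and 969 lower in seu-6 in both mocks, where independent lists would share 492.1 and 332.6. The log2 differences correlated across genes with Pearson r = 0.460 and Spearman rho = 0.361, and genes are not independent replicates. NaCl and sorbitol called 1267 genes higher and 1235 lower in Col-0 by both, against 979 and 1210.0 for independent lists. In opposite directions, 949 were higher by NaCl and lower by sorbitol and 1589 lower by NaCl and higher by sorbitol, against 974.9 and 1214.7. The log2 changes had r = 0.017 across genes. Age, duration, agent and dose all differ between the experiments, so none of them can be set apart from the others.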

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

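Among the tests below, those of seed RNA, of storage genes active in any medium, of background reads and of abundant transcripts were chosen after the result was seen, as was the matching used in the test of a uniformly smaller sorbitol response. The tests of transfer into liquid and of other splits were chosen before.

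Results are gathered here because the test of the difference between genotypes was passed. The NaCl responses differed in 1585 genes and the sorbitol responses in 2812 by edgeR. The median differences of the responsive genes were -0.055 for those up under NaCl, and -0.090 and 0.074 for those up and down under sorbitol. In the NaCl interaction the list medians were -0.20 for ABA effectors, 0.15 for ABA receptors, 0.45 for CBF/DREB and ERF factors, 0.14 for ZAT, WRKY and MYB factors, 0.060 for touch genes and -0.57 for jasmonate genes. The other medians there were -0.064 for proline and raffinose genes, -0.20 for aquaporins, -0.14 for auxin genes, -0.12 for SEUSS partners, 0.36 for heat shock genes, 0.14 for immune genes and -0.24 for root markers. With an estimated correlation 2 of these lists stayed under an adjusted p of 0.05, those of jasmonate and of CBF/DREB and ERF genes. Leaving out 1 library ended the call of some lists. For ABA receptors the camera adjusted p was then 0.072 and 0.15 without replicate 2 of the Col-0 or seu-6 mock, and 0.053 and 0.14 without NaCl replicate 2 of Col-0 or seu-6. For proline genes it was 0.099 and 0.076 without replicate 2 of the Col-0 or seu-6 mock, 0.14 without NaCl replicate 1 of Col-0 and 0.076 without NaCl replicate 2 of seu-6. For root markers it was 0.084 and 0.11 without replicate 1 of the Col-0 or seu-6 mock, 0.068 without NaCl replicate 1 of Col-0 and 0.076 without NaCl replicate 2 of seu-6. For auxin genes it was 0.092 without seu-6 mock replicate 1, and for SEUSS partners 0.060 and 0.070 without Col-0 mock replicate 1 or seu-6 mock replicate 2. The call of the NaCl-induced genes was lost without any 1 of the 4 seu-6 libraries of that experiment, with medians between -0.045 and -0.033. In the sorbitol interaction the medians were -0.58 for ABA effectors, -0.17 for ABA synthesis, -0.67 for PP2C and ABF genes, -0.19 for jasmonate genes, -0.19 for proline genes and -0.099 for aquaporins. Auxin genes had 0.23, light harvesting genes 0.087 and cell wall enzymes 0.26. The aquaporin call was lost without sorbitol replicate 2 of Col-0 (0.074) or replicate 1 or 2 of seu-6 (0.051 and 0.053). There the ABA effectors and the PP2C and ABF list stayed under 0.05 with an estimated correlation.

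Single genes that passed the NaCl interaction with a lower log2 response in seu-6 were OPR3 (-0.85), CYP94C1 (-1.45), LOX2 (-0.84), LOX3 (-0.71), ABR1 (-2.54), JRG21 (-2.08), LTI78 (-0.62), ERD7 (-0.42), PIP2A (-0.30) and PIF4 (-0.41). Those with a higher one were NUDT21 (1.40), NUDT4 (1.76), ORA47 (1.89), DREB2A (1.08), ERF6 (0.51), STZ (0.86), RHL41 (1.19), CML38 (0.84), TCH2 (0.57), HSP70 (0.59) and PR1 (1.201). The sorbitol interaction was lower in seu-6 for COR15A (-0.78), KIN2 (-0.68), COR47 (-0.58), LTI30 (-0.75), PP2CA (-0.81), HB-7 (-0.96), HAB1 (-0.66), ABF2 (-0.74), P5CS1 (-0.61), SUS3 (-1.46), CYP94B3 (-2.34), SAG29 (-3.44), PIP1C (-0.51) and AAO3 (-0.57). It was higher for XTH15 (1.34), EXPA1 (0.60), EXPA8 (1.38), IAA29 (1.68), ESM1 (0.86), DREB1A (1.67) and BGL2 (0.87).

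Some shares of reads are listed because they lay outside those of Col-0 at 6 h and enter no comparison. Reads in no feature were 2.51% in seu-6 6 h mock replicate 1, and 1.85% and 2.19% in seu-6 sorbitol replicates 1 and 2, against 0.978% to 1.198% in Col-0. Reads with more than 1 alignment were 4.48% and 2.35% in seu-6 6 h mock replicates 1 and 2 and 2.995% and 3.08% under sorbitol, against 2.11% to 2.197%. Plastid genes held 0.095% in seu-6 6 h mock replicate 1, and 0.049% and 0.043% under sorbitol, against 0.026% to 0.032%.

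Seed storage and oil body transcripts summed to between 185.3 and 186.1 CPM in the seu-6 6 h mock, against 2.78 in the highest other library. RNA of mature seeds is argued against, since late embryogenesis transcripts were at most 0.023 of the storage transcripts and, at 3.97 to 4.29 CPM, below the highest Col-0 mock library at 5.85. Storage genes active in seu-6 whatever the medium are argued against by the next highest seu-6 group, at 0.015 of the 6 h mock. RNA of developing seeds or embryos stays open as a candidate source, since summed embryo regulators reached at least 1.68 CPM in both libraries, against at most 0.264 in the Col-0 6 h mock and 0.924 in the highest other library, a Col-0 sorbitol library. ABI3 alone gave 47 of 81 and 26 of 73 of these counts, LEC2 had 4 and 0 counts in both genotypes, and no test separates that source from embryo genes expressed in the seedlings of this group.

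The smaller sorbitol response of ABA effectors in seu-6 could come in part from the 6 h mock, where their median in seu-6 against Col-0 was 0.18. The effectors were also lower in seu-6 under sorbitol itself, where no mock enters, with a median of -0.46. Its SE of 0.080 is from a bootstrap over genes and does not measure the spread between libraries. Background reads within genes would lower genes of 1 level alike. The 20 genes nearest in level to each effector had a median of 0.0025 in the same comparison, near the -0.00046 of all genes. This argues against background for the lower effector levels under sorbitol only. Matching used levels under sorbitol, so background in the seu-6 6 h mock, where effector levels were lower, was not tested. A response that is smaller for all genes alike stays open: the median interaction was at percentile 14.05 of 10000 random lists matched on response and level. Those lists had a median response of 3.04 against 3.36 in the effectors, so the matching remained uneven, and the PP2C and ABF list lay at percentile 3.1 with 2.95 against 3.001. A first matching on ranks, replaced after its result was seen because its random lists responded by 1.46 and 1.49 only, had placed the lists at percentiles 0 and 0.01.

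The fall of touch, ZAT and jasmonate transcripts under NaCl may reflect genes raised in the mock by transfer into liquid, which would then lie higher 15 min than 6 h after it. In Col-0 13 of 15 touch genes were called higher in the 15 min mock than in the 6 h mock, as this explanation needs, with 26 of 26 ZAT, WRKY and MYB factors and 23 of 23 jasmonate genes. Lists that did not fall as a whole under NaCl were higher there too, heat shock genes in 11 of 15 and ABA effectors in 19 of 24 cases (camera adjusted p = 0.0095 and 0.022 with an estimated correlation), so this does not single out the lists that fell. Age and experiment differ along with the time since transfer, so these stay open as well. A rise of a few abundant transcripts that would lower the share of others is argued against, since the 20 highest genes changed by -0.404 percentage points of counts in Col-0 and -0.423 in seu-6.

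Other splits of the 8 libraries of an experiment, 4 against 4, were counted for the mean responses in a 2-group fit. For NaCl 1 of 35 splits, the real one, reached 4065 called genes, the highest other being the split by genotype with 2633. For sorbitol 1 of 35 reached 11363, the highest other calling 608. All splits by neither treatment nor genotype called 0 genes, since they leave the treatment effect in the residual spread of the 2-group fit. The counts therefore do not measure how often chance division of the libraries would give such numbers.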

How the results depend on the processing

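No called named gene changed direction under an alternative, and neither did any list called in both fits. A list that changed direction and lost its call was counted among those lost. For the estimated correlation the direction was taken from the main test. The median of genes down under NaCl, which was not called, lay between -0.025 and 0.036 with 1 library left out. Counted once per gene, comparison and setting, 4729 tests of named genes stayed and 41 were lost over the other alternatives. The numbers were 7419 and 213 when 1 library was left out. DESeq2 called 2037 genes in the sorbitol interaction, against 2812 with edgeR. Between genotypes in the 6 h mock it called 4821, against 6013. Of list tests 727 stayed, 95 were lost and 6 gained, and 2129, 34 and 45 when 1 library was left out. Tests that stayed include those of lists called in neither fit. Of the 95 lost, 91 were lost with an estimated correlation, where 185 stayed. With an estimated correlation fewer lists were called: 5 under NaCl in Col-0, 3 in seu-6, 6 in the mean NaCl response, 5 between genotypes under NaCl and 2 in the NaCl interaction. With DESeq2's size factors and the preset correlation these numbers were 12, 13, 12, 12 and 13. For sorbitol these were 4 in Col-0, 4 in seu-6, 4 in the mean response, 4 between genotypes in the 6 h mock, 5 under sorbitol and 2 in the interaction. On raw library totals SEU in the Col-0 6 h mock was 57.2 CPM. Leaving out 1 library, genes called higher under NaCl in Col-0 lay between 2315 (without NaCl replicate 2 of Col-0) and 3644, and genes with a lower NaCl response in seu-6 between 619 (without NaCl replicate 1 of Col-0) and 964. The median of NaCl-induced genes lay between -0.081 and -0.033 and was not called without any 1 of the 4 seu-6 libraries of that experiment. The overlap of NaCl-induced genes with those lower in seu-6 lay between 482 (without NaCl replicate 1 of Col-0) and 856. The correlation of genotype effects between mocks lay between 0.437 and 0.464, and that of the NaCl and sorbitol responses between 0.010 and 0.024, across genes.

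Replicate numbers did not pair the libraries, with correlations of deviations between -0.036 and 0.020 for NaCl and between -0.049 and 0.071 for sorbitol. With the number as a replicate block edgeR called 1593 genes in the NaCl interaction, 2726 in the sorbitol interaction, 7341 under NaCl and 13459 under sorbitol in Col-0.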

Other observations

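All tests in this part were chosen after the result was seen. Phosphate starvation genes, which plants raise when phosphate is scarce, were lower in seu-6 in the 15 min experiment, where SPX3 and IPS1, which the list holds, had drawn attention to them. In the mock SPX1 (AT5G20150) had a log2 fold change of -1.86 ± 0.079, the sulfolipid synthesis gene SQD2 (AT5G01220) -0.98 ± 0.043 and PS2 (AT1G73010) -2.16 ± 0.073, with edgeR adjusted p of 3.0e-34 or lower. Of 19 genes in the list 19 were lower in the mock with a median of -1.37, and 18 under NaCl with a median of -1.54. The camera p with an estimated correlation was 3.3e-04 and 2.2e-04. In the 6 h mock 5 were higher and 3 lower, and under sorbitol 3 and 3. As a list they were not lower in seu-6 there, with medians of 0.083 in the 6 h mock and 0.025 under sorbitol. The highest camera p with an estimated correlation over the 4 genotype comparisons was 0.958, which does not show that an effect is absent. In Col-0 the list summed to 333 and 336 CPM in the 6 h mock libraries and 532 and 562 under sorbitol. The 15 min mock libraries had 816 and 821 CPM. In seu-6 it summed to 357.0 and 368.0 CPM in the 6 h mock libraries, above Col-0. Under sorbitol it summed to 526.7 and 525.7 CPM in seu-6, slightly below Col-0. With the medians of 0.083 and 0.025, these sums argue against a fall of the list at 6 h as large as that at 15 min. Col-0 levels in the mock were lower at 6 h than at 15 min, so a smaller fall, or one in genes with few counts at 6 h, was not excluded. Whether the plates of both genotypes held the same phosphate is not given in the sources used here, so a difference in medium was not tested. Sorbitol raised 14 and lowered 2 of the 19 in Col-0, and 13 and 1 in seu-6, with camera p of 0.033 and 0.019 with an estimated correlation.

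Seed storage and oil body genes were higher in seu-6 in the 6 h mock in 12 of 12 cases (camera p of 7.7e-05 with an estimated correlation). That list was written after CRU3, SESA3, CRU2 and CRA1 were seen and holds them, so it is not independent evidence, and the lower values in seu-6 under sorbitol rest on the same 2 mock libraries. Late embryogenesis genes of seeds rose under sorbitol in 6 of 7 cases in Col-0 and in 6 in seu-6, with 1 lower (camera p of 0.10 and 0.13 with an estimated correlation). Embryo regulators held 3 genes with enough counts, of which 1 was higher in seu-6 in the 6 h mock (camera p of 0.19 with an estimated correlation). The locus AT4G29200 had between 535 and 1441 counts in seu-6 libraries and at most 4 in those of Col-0. Whether this comes from the insertion or the background of the line is not given in the sources used here, and with 1 mutant line compared, differences between genotypes are not assigned to SEU alone.

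Over the 16 libraries the first principal components held 44.1%, 19.1%, 11.5% and 8.16% of the variance.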
